A study of Mus musculus with 9 samples.

How the data were processed

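Total RNA from the gastrocnemius, the large calf muscle, of C57Bl6J mice about 8 weeks old was sequenced after dissection, freezing in Trizol, column purification and a stranded total RNA library preparation, per the labels' protocols. The design has 3 groups of 3 libraries. CTL came from unirradiated mice, RL from the irradiated hind limb and CL from the opposite limb of the irradiated mice. Irradiation was given at 4 weeks of age as 3 sessions of 8.2 Gy, and muscles were taken 3 weeks later, per the series description. Mouse numbers in the labels show 6 animals. CL and RL libraries with the same replicate number come from the same mouse, while the CTL mice are other animals, so replicates within a group are separate animals.

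The authors deposited raw read counts per gene for each library, and these counts are the values tested here. Reads were assigned to GRCm38.p5 and analysed with DESeq2, per the submitters' processing notes, and the aligner, the counting program, its strand setting and the annotation are not given in the sources used here. A second deposited table holds a normalised signal per library, which equals the counts divided by 1 size factor per library to within a relative deviation of 5.4e-10. For each comparison the authors deposited a log2 fold change, a test statistic (a score), a p-value and an adjusted p-value from their own fit, together with a mean signal over the libraries of that fit. This mean differed by more than 1% from the mean of the 9 normalised columns for 82.9% of 11273 genes, so the authors' calls and those made here do not rest on identical inputs. A table of regularised log values was not used here.

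The count table has 49568 gene rows. Of these, 26 had names that a spreadsheet had turned into dates, which hold at most 0.0536% of a library's counts, and 21023 had no count in any library. Gene symbols were matched to GENCODE vM21 on GRCm38 for 47114 rows, through an older symbol for 447 more, and 2007 rows stayed unmatched. Coordinates are 1-based and from that annotation. Transcript sequences of the same annotation were searched for a repeat, and the genome sequence was not used here. Since the counting rules are not stated, genes with near-identical copies and overlapping genes are uncertain.

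Library totals ran from 30.8 to 44.6 M counts. Mitochondrially encoded genes, mostly ribosomal RNA, took 31.1% to 51.8% of the counts and Ttn, which encodes titin, took 10.5% to 18.1%. CPM values are edgeR's counts scaled to the library total, with the total adjusted by the trimmed mean of M values. Replicates were compared by chi-square over 9420 genes, and every pair differed by more than counting noise, with a smallest chi-square per degree of freedom of 19.0. Values are given as mean ± SD over 3 libraries and log2 fold changes with a standard error (SE). This SE is the absolute log2 fold change divided by the square root of edgeR's F statistic from the fit of all 9 libraries. The interval given for a ratio of counts is an exact 95% interval that covers counting error only.

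The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) on the raw counts of all 9 libraries in 1 fit without covariates, after edgeR's expression filter by group, which kept 14986 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no fold limit. All 9 libraries entered 1 fit so that the 3 small groups share an estimate of the spread. Gene lists were tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 32 lists within a comparison. Camera was repeated with an estimated correlation between genes. The 33 lists held 534 entries, were written from textbook knowledge and none was chosen on these libraries. Which lists are described gene by gene was decided after the list results were seen. Of the 33 lists 32 were tested, and the list of sex-linked genes served only to check the libraries. For each described list, the members past the edgeR test are also counted with the p-values adjusted over the list alone.

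The genes named by rule are, in each comparison, the 8 with the highest and the 8 with the lowest log2 fold change among called genes with a mean log2 CPM of at least 1, a regular gene symbol, and all 3 libraries of a group above all 3 of the other. To these come up to 4 members with the smallest p of each described list, and always Pax7, Cdkn1a, Myh4, Col1a1 and Chrng. A gene that is named outside this rule is said to be chosen after its values were seen, and the values of 1 further gene are not reported here. Groups, tests, lists, this rule and the alternatives were fixed before the data were examined, except for the alternatives without CL 1 in the comparison of RL with CTL and without the mouse of CL 1 and RL 1, which were added after the libraries had been seen.

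The procedure was tested on simulated data for RL vs CTL, with counts drawn from the real means and library sizes and 200 changed genes among 14780 tested. It recovered 87% of genes changed by a log2 of 1 and 99% of those changed by a log2 of 2, with 6 false calls among 192, 0 calls in the unchanged contrast, and a planted list of 20 genes called at an adjusted p of 2.1e-42 with 0 other lists. These shares need not hold for the real libraries. There the calls of RL vs CTL went from 77 to 600 without CL 1. The lists that camera called went from 20 to 1 with an estimated correlation.

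Alternatives were DESeq2 1.42.0, limma-voom, DESeq2's size factors in edgeR, no filter, a mean count of at least 10, a fold limit of log2 1, a fit of the 6 libraries of a comparison alone, mitochondrially encoded genes left out, each library left out in turn, the replicate number as a block, and limma-voom with the mouse as a random effect. For RL vs CL the block is the mouse, since the labels tie the limbs to an animal. Deviations from the group means correlated at 0.294, 0.429 and 0.0716 for the limbs of the same mouse, and the random-effect correlation was 0.324. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9, and transcripts were searched with BLAST+ 2.17.0.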

Results

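The data are total RNA-seq profiles of the gastrocnemius from mice irradiated on 1 hind limb before puberty, taken 3 weeks after 3 sessions of 8.2 Gy. The irradiated limb (RL), the unirradiated limb of the same mice (CL) and a limb of unirradiated mice (CTL) were each profiled in 3 animals. CTL libraries held 41.8, 30.8 and 36.5 M counts, CL libraries 41.5, 44.6 and 40.1 M, and RL libraries 37.7, 42.1 and 42.8 M. All 9 libraries had at least 2045 counts for the Y-linked gene Ddx3y and at most 4 for Xist, the transcript that silences an X chromosome in females. The stated aim is to find expression changes caused by radiation, the title names the Pax7-expressing stem cells of young muscle, and the 3 comparisons address the irradiated limb, the distant limb and the difference between the limbs of a mouse.

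**Figure D1:**
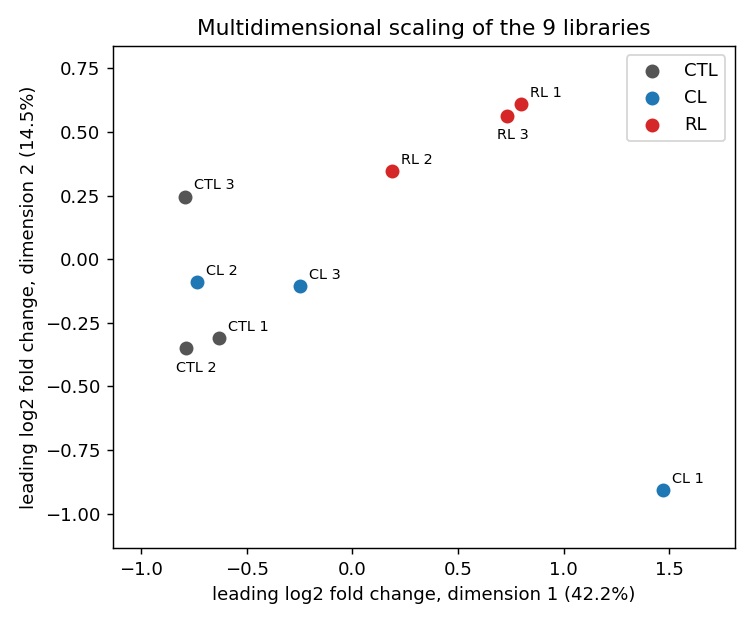
Multidimensional scaling of the 9 libraries, with the leading log2 fold change on dimension 1 (42.2% of the variance) on the x axis and on dimension 2 (14.5%) on the y axis, 1 point per library coloured by group. The RL libraries lie above the CTL libraries on both axes, and CL 1 stands apart from all others at 1.47 and -0.91.

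CL 1 was the library farthest from the rest, with a median correlation of 0.969 to the other libraries, and CTL 1 and CL 2 were the closest pair at 0.990. Counts of changed genes are therefore also given without CL 1.

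Irradiated muscle was compared with muscle of unirradiated mice to find what the treated limb had lost or gained. Markers of satellite cells, the resident stem cells of muscle, fell in RL. Pax7, the transcription factor that defines these cells (chromosome 4, 139737062 to 139833528, minus strand), went from 1.79 ± 0.399 CPM in CTL to 0.490 ± 0.157 CPM in RL (SD, n = 3 each), a log2 fold change of -1.87 ± 0.30 (SE, adjusted p = 0.0256). Calcr, the calcitonin receptor that keeps satellite cells quiescent, fell by 2.13 on the log2 scale (adjusted p = 0.0256), and Chodl, a membrane lectin, by 1.15 (adjusted p = 0.0271). The satellite cell factor Myf5 went from 0.787 ± 0.0968 to 0.289 ± 0.0473 CPM (SD, n = 3), a log2 fold change of -1.44 that did not pass by edgeR (adjusted p = 0.0526) and did by DESeq2 (adjusted p = 0.0317). Of the 20 tested satellite cell markers, 3 fell over all genes, 0 rose and 17 did not pass. Adjusted over the list alone 10 fell and 1 rose, the surface proteoglycan Sdc3, named after its value was seen. The list median was -0.37 (camera adjusted p = 2.61e-07; adjusted p = 0.0701 with an estimated correlation). The Pax7 call ended when any library of either group was left out alone, with adjusted p = 0.104, 0.110 and 0.0790 without CTL 1, 2 and 3 and 0.0817, 0.0681 and 0.181 without RL 1, 2 and 3, at log2 fold changes between -2.15 and -1.67. The Pax7 call held without CL 1, and also without the mouse of CL 1 and RL 1. In the fit without CL 1, 6 of the markers fell and 1 rose over all genes.

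Target genes of p53, the DNA damage response factor, rose in RL. Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727, plus strand), stood at 1.83 ± 0.307 CPM in CTL, 3.80 ± 1.58 in CL and 11.6 ± 2.17 in RL (SD, n = 3), a log2 fold change of 2.66 ± 0.27 (SE) between RL and CTL with adjusted p = 0.00278. It was called in all 6 fits that left out a library of these groups. Over all genes Cdkn1a alone of the 23 tested members passed and 22 did not. In the fit without CL 1, 11 of 24 tested rose and 0 fell over all genes. With all libraries and adjusted over the list alone 12 rose and 0 fell. These include Trp53inp1, an autophagy and apoptosis regulator (log2 0.72), Sesn2, a stress-induced inhibitor of growth signalling (1.47), and Bax, a pore-forming apoptosis effector (0.95), whose adjusted p over all genes were 0.0648, 0.0651 and 0.0660 by edgeR and 0.00198, 0.00814 and 0.0135 by DESeq2. The list median was 0.71 (camera adjusted p = 8.63e-11), and this was the 1 list of the comparison still called with an estimated correlation (adjusted p = 0.00892 with an estimated correlation).

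**Figure D2:**
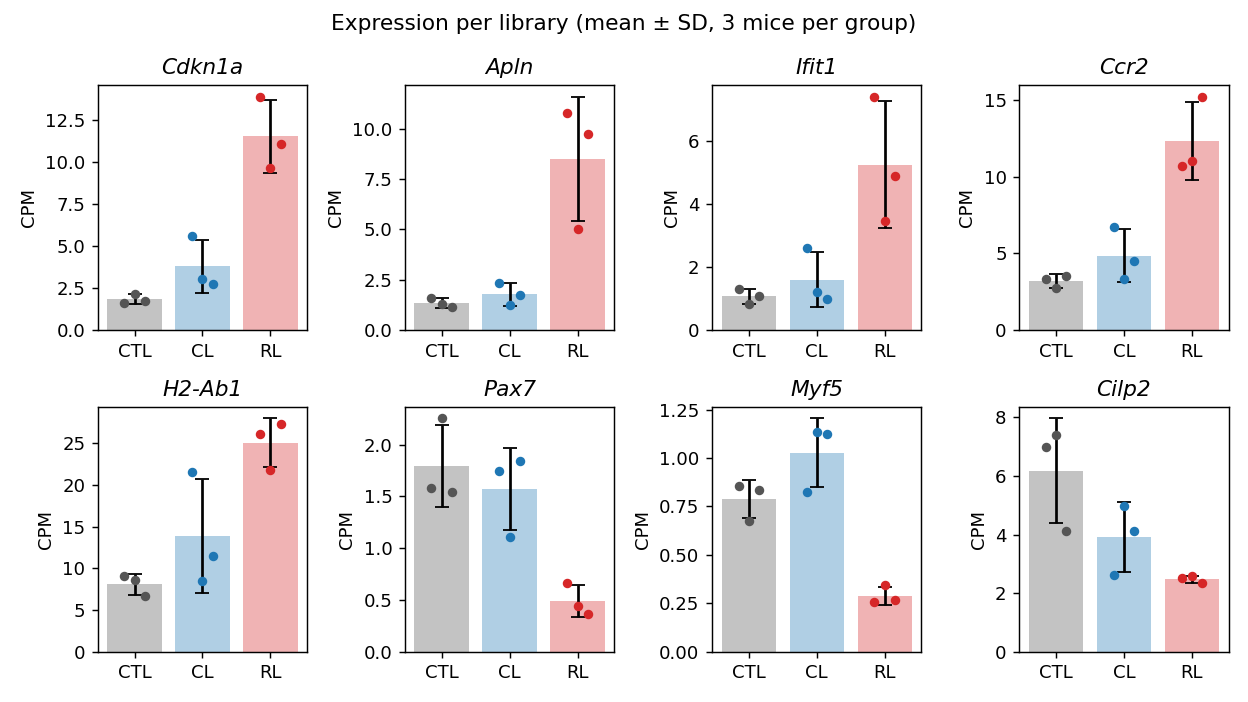
Expression of 8 genes in CPM (y axis) in each library, with points for the 3 libraries of CTL, CL and RL, bars for the mean and error bars for the SD. Cdkn1a, Apln, Ifit1, Ccr2 and H2-Ab1 are highest in RL, where Pax7, Myf5 and Cilp2 are lowest.

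Genes of the interferon response rose in the irradiated limb. Ifit1, an antiviral RNA-binding protein, rose from 1.06 ± 0.244 to 5.26 ± 2.01 CPM (SD, n = 3), a log2 fold change of 2.30 ± 0.37 (SE, adjusted p = 0.0271). Irf7, a transcription factor that drives interferon expression, rose by 2.64 (adjusted p = 0.0333), the ubiquitin-like modifier Isg15 by 2.44 (adjusted p = 0.0163) and Ifi44 by 1.87 (adjusted p = 0.0163). Of 22 interferon response genes tested, 6 rose, 0 fell and 16 did not pass over all genes. With p-values adjusted over the list alone 21 rose. The list median was 1.43 (camera adjusted p = 2.12e-23; adjusted p = 0.147 with an estimated correlation). Without CL 1, 17 of its members rose over all genes.

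Macrophage markers and antigen presentation genes were also higher as groups by camera. Ccr2, the chemokine receptor of recruited monocytes, went from 3.19 ± 0.435 to 12.3 ± 2.52 CPM (SD, n = 3), a log2 fold change of 1.95 ± 0.24 (SE, adjusted p = 0.00937), and Itgam, an integrin chain of myeloid cells, rose by 1.51 (adjusted p = 0.0333). The complement component C1qa was higher by 1.10 without passing by edgeR (adjusted p = 0.0764) and passed by DESeq2 (adjusted p = 0.00311). Over all genes 2 of 17 macrophage markers rose, 0 fell and 15 did not pass, and adjusted over the list alone 13 rose, with a list median of 1.18 (camera adjusted p = 1.38e-12; adjusted p = 0.300 with an estimated correlation). H2-Ab1, a chain of the class II antigen presenting complex, rose from 8.11 ± 1.26 to 25.1 ± 2.94 CPM (SD, n = 3), a log2 fold change of 1.63 (adjusted p = 0.0317). It was the 1 of 14 antigen presentation genes to pass over all genes, where 13 did not, and adjusted over the list alone 10 rose, with a median of 1.11 (camera adjusted p = 8.22e-10; adjusted p = 0.338 with an estimated correlation). Without CL 1, 11 genes of each of these lists rose over all genes. Of the 16 lymphocyte markers 3 had enough counts to be tested and 0 passed over all genes by edgeR; adjusted over the list alone 1 rose, and the median of 2.03 (camera adjusted p = 0.0171; adjusted p = 0.397 with an estimated correlation) was no longer called without CTL 3 (adjusted p = 0.0771).

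Tendon genes were lower in RL. Cilp2, a cartilage and tendon matrix protein, fell from 6.18 ± 1.79 to 2.47 ± 0.125 CPM (SD, n = 3), a log2 fold change of -1.33 ± 0.25 (SE, adjusted p = 0.0449), and the fibrillar collagen chain Col11a1 fell by 1.02 (adjusted p = 0.0365). The matrix protein Chad (log2 -1.37, adjusted p = 0.0518) and the small proteoglycan Fmod (log2 -0.90, adjusted p = 0.0634) did not pass by edgeR and did by DESeq2 (adjusted p = 7.89e-04 and 0.00133). Of 10 tenocyte markers 2 fell, 0 rose and 8 did not pass over all genes (7 fell without CL 1). With all libraries and adjusted over the list alone 8 fell. Their median was -0.82 (camera adjusted p = 8.22e-10; adjusted p = 0.102 with an estimated correlation).

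Markers of pericytes, Schwann cells and the extracellular matrix gave few single calls. Pdgfrb, a growth factor receptor of pericytes, fell by 0.59 on the log2 scale (adjusted p = 0.0361). It was the 1 of 11 pericyte and smooth muscle markers to fall over all genes while 10 did not pass. With p-values adjusted over the list alone 3 fell, and the median was -0.23 (camera adjusted p = 0.00373; adjusted p = 0.127 with an estimated correlation). Among Schwann cell markers, Prx and Drp2, both needed for myelin, had log2 fold changes of -0.65 (adjusted p = 0.0985) and -0.67 (adjusted p = 0.116, and 0.0463 by DESeq2). Of the 15 tested, 3 had positive fold changes, among them Egr2. It had 0.301, 0.620 and 0.327 CPM in CTL 1, 2 and 3 and 1.13, 0.563 and 1.19 CPM in RL 1, 2 and 3. Over all genes 0 of 15 passed by edgeR, adjusted over the list alone 2 fell, and the median was -0.50 (camera adjusted p = 1.90e-04; adjusted p = 0.338 with an estimated correlation). Among extracellular matrix genes the small proteoglycan Lum rose by 0.71 (adjusted p = 0.0449), 25 of 26 did not pass and 0 fell. Adjusted over the list alone 2 rose, Lum and the matricellular gene Ctgf. Their median of 0.22 (camera adjusted p = 0.00416; adjusted p = 0.661 with an estimated correlation) was not called without CTL 3 (0.098, adjusted p = 0.138) or RL 1 (0.13, adjusted p = 0.0819), nor without the mouse of CL 1 and RL 1 (0.13, adjusted p = 0.131). Col1a1, the main collagen of muscle connective tissue, had a log2 fold change of -0.43 ± 0.33 (SE, adjusted p = 0.672). Aqp1, an endothelial water channel chosen after its values were seen, fell by 0.74 as the 1 endothelial marker of 16 to pass, in a list that was not called (median -0.15, adjusted p = 0.0941).

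Contractile genes of the myofibre did not pass singly by edgeR. Myh4, the myosin of the fastest fibres, had a log2 fold change of -0.41 ± 0.17 (SE, adjusted p = 0.360), the calcium store protein Casq1 -0.56 (adjusted p = 0.107) and the fast fibre actin crosslinker Actn3 -0.51 (adjusted p = 0.160). DESeq2 called Casq1 (adjusted p = 0.00315), Actn3 (adjusted p = 0.00887), the myosin-binding protein gene Mybpc2 (adjusted p = 0.0178) and the troponin gene Tnnt3 (adjusted p = 0.0431) lower. EdgeR called Casq1 without CL 1 (adjusted p = 0.0269). Of 15 fast fibre genes 0 passed over all genes by edgeR, adjusted over the list alone 5 fell, and their median was -0.27 (camera adjusted p = 2.22e-05; adjusted p = 0.338 with an estimated correlation). Of 13 slow fibre genes 0 passed over all genes and 0 adjusted over the list alone by edgeR, and 0 had an unadjusted p under 0.05. Their median of 0.28 (camera adjusted p = 0.0283; adjusted p = 0.586 with an estimated correlation) was not called without CTL 1 (adjusted p = 0.182), CTL 3 (adjusted p = 0.208), RL 2 (adjusted p = 0.232) or RL 3 (adjusted p = 0.104). Chrng, the fetal subunit of the acetylcholine receptor, had too few counts to be tested, with 0.0593 ± 0.0825 CPM in RL and 0.0183 ± 0.0160 CPM in CTL (SD, n = 3).

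Proliferation genes were higher as a group. Mki67, a marker of dividing cells, had 1.46 ± 0.283 CPM in CTL, 4.45 ± 5.21 in CL and 6.02 ± 1.85 in RL (SD, n = 3), and the log2 fold change of RL against CTL, 2.03 ± 0.68 (SE), did not pass (adjusted p = 0.232). Of 20 tested proliferation genes 0 passed over all genes and 0 adjusted over the list alone by edgeR, although 7 had an unadjusted p under 0.05, and without CL 1, 5 rose over all genes. DESeq2 called Ccnb2, a mitotic cyclin (log2 3.56 by edgeR, adjusted p = 0.144, and 0.0374 by DESeq2). Their median was 1.00 (camera adjusted p = 1.74e-06; adjusted p = 0.338 with an estimated correlation), and 0.52 without the mouse of CL 1 and RL 1 (adjusted p = 1.82e-06). Circadian clock genes moved both ways, with the clock activator Arntl at a log2 fold change of 0.82 (adjusted p = 0.0518) and the clock repressors Per3 at -0.79 (adjusted p = 0.0523) and Cry2 at -0.58 (adjusted p = 0.0526), which DESeq2 called at adjusted p = 0.00134, 6.58e-04 and 0.00255. Over all genes 0 of 16 passed by edgeR and 10 had an unadjusted p under 0.05; adjusted over the list alone 3 rose and 7 fell, with a list median of -0.27 (camera adjusted p = 0.00242; adjusted p = 0.147 with an estimated correlation). Of the 7 mitochondrially encoded genes tested, 0 passed over all genes or adjusted over the list alone by edgeR and 1 had an unadjusted p under 0.05; their median was 0.41 (camera adjusted p = 0.00271; adjusted p = 0.519 with an estimated correlation) and was not called without CTL 2 (0.12, adjusted p = 0.0734).

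Further genes with large changes were Apln, the ligand of the apelin receptor, which rose from 1.34 ± 0.233 to 8.51 ± 3.08 CPM (SD, n = 3), a log2 fold change of 2.65 ± 0.31 (SE, adjusted p = 0.00864), and the cell cycle entry cyclin Ccnd1, which rose by 1.85 (adjusted p = 0.0226). Tlr8, an endosomal RNA sensor, and Lyz1, a lysozyme, rose by 1.85 (adjusted p = 0.0449) and 1.70 (adjusted p = 0.00937). The actin-binding protein gene Clmn fell by 1.31, the secreted factor Angptl7 by 1.25, the guidance molecule Sema6a by 1.07, the glucose transporter Slc2a3 by 1.01 and the glycosylation enzyme Galnt15 by 0.99, with adjusted p between 0.0117 and 0.0436.

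In total 77 genes changed between RL and CTL, 50 higher and 27 lower in RL, by edgeR. All 77 had groups that did not overlap, as did 3102 of 14986 tested genes (20.7%, where 10% come by chance). The authors' deposited table has 361 genes past an adjusted p of 0.05, 243 higher and 118 lower, which include 76 of these 77. The count was 600 (455 higher, 145 lower, all 77 included) without CL 1, a library of the group outside this comparison that enters through the shared spread, 505 in a fit of the 6 libraries alone and 333 by DESeq2. It was 6, 2 and 12 without CTL 1, 2 and 3, and 5, 51 and 2 without RL 1, 2 and 3. Of the 25 named genes that passed, 3, 1 and 7 stayed called without CTL 1, 2 and 3, and 4, 15 and 1 without RL 1, 2 and 3. All 25 stayed called without CL 1, and also without the mouse of CL 1 and RL 1.

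**Figure D3:**
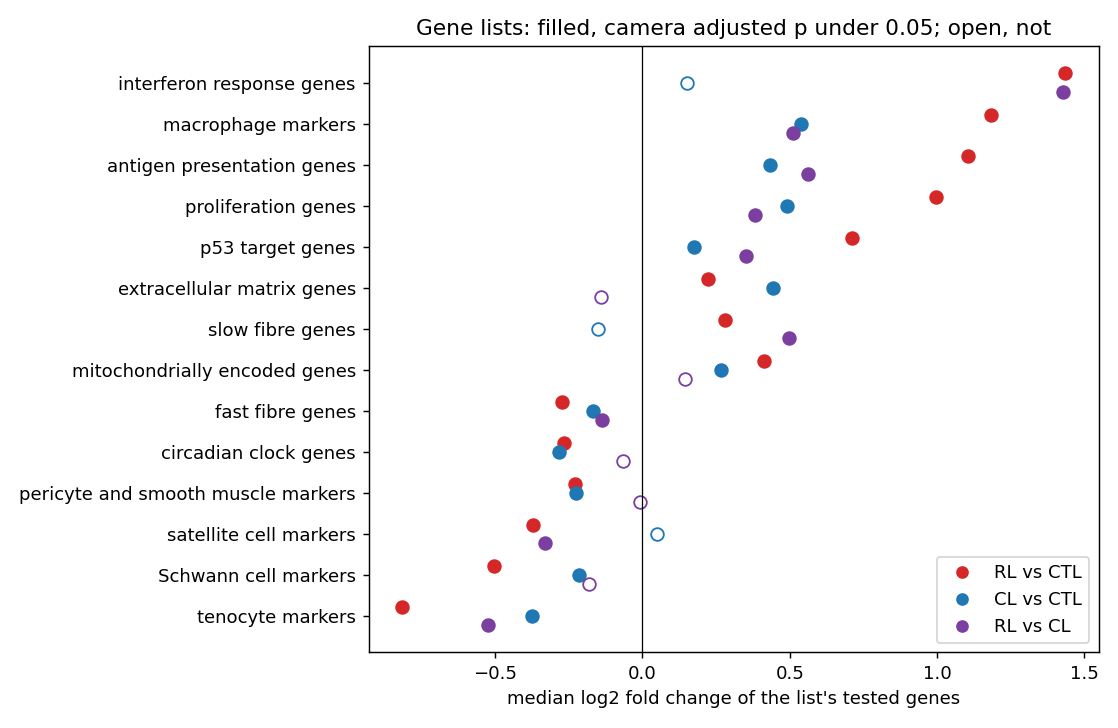
Median log2 fold change (x axis) over the tested genes of 14 lists (y axis), with 1 point per comparison, filled where the camera adjusted p was under 0.05 and open elsewhere. The interferon response genes lie at 1.43 in both comparisons that hold RL and at 0.15 in CL vs CTL, and the tenocyte markers lie below 0 in all 3.

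Camera called 20 of the 32 lists, 11 higher and 9 lower, and all 20 also without CL 1. Beyond those described, neuromuscular junction genes (median -0.14), erythroid genes (-0.35) and glycolysis and glycogen genes (-0.20) were lower, and senescence and secretory genes (0.59) and immediate early genes (0.53) were higher, with adjusted p between 6.10e-04 and 0.0383 (adjusted p of 0.519 to 0.586 with an estimated correlation). Calls ended without RL 1 for the erythroid genes, RL 2 for glycolysis and glycogen genes, CTL 3 or RL 2 for neuromuscular junction genes, CTL 3 for immediate early genes, and CTL 1, CTL 3 or RL 1 for senescence and secretory genes, at adjusted p between 0.0508 and 0.609.

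The unirradiated limb of the irradiated mice was compared with the control mice to ask whether irradiation was felt at a distance. No gene passed by edgeR. Pax7 stood at 1.57 ± 0.398 CPM in CL and 1.79 ± 0.399 CPM in CTL (SD, n = 3), a log2 fold change of -0.19 ± 0.27 (SE, adjusted p = 0.934). Cdkn1a had a log2 fold change of 1.07 ± 0.27 (SE, adjusted p = 0.692), which was 0.66 without CL 1, Myh4 -0.29 ± 0.17 (SE, adjusted p = 0.807) and Col1a1 0.56 ± 0.33 (SE, adjusted p = 0.809), which became -0.021 without CL 1. By edgeR 0 genes were called, 996 had an unadjusted p under 0.05 (668 higher, 328 lower), and the lowest adjusted p was 0.105. DESeq2 called 16 (5 higher, 11 lower), limma-voom 0, and the authors' deposited table has 12 (5 higher, 7 lower). Groups did not overlap in 1408 genes (9.40%, where 10% come by chance). Without CTL 3, edgeR called 1 gene.

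Lists of genes showed small differences in CL. Target genes of p53 had a median of 0.17 (camera adjusted p = 0.0344, and 0.484 with an estimated correlation). That call ended without CL 1 (0.11, adjusted p = 0.180), CL 3 (adjusted p = 0.0668), CTL 1 (adjusted p = 0.0550) or CTL 3 (adjusted p = 0.122). Over all genes 0 of 23 passed by edgeR, and adjusted over the list alone 1 rose. Macrophage markers were higher by a median of 0.54 (camera adjusted p = 2.65e-07; adjusted p = 0.500 with an estimated correlation), which was 0.27 without CL 1 (adjusted p = 0.00709); 0 of 17 passed over all genes or adjusted over the list alone by edgeR, and 9 had an unadjusted p under 0.05. Lyz2, a lysozyme of macrophages, had 24.8 ± 4.62 CPM in CTL and 52.6 ± 34.4 in CL (SD, n = 3), a log2 fold change of 1.08 that was 0.41 without CL 1. Pericyte and smooth muscle markers were lower by a median of -0.22 (camera adjusted p = 1.41e-04; adjusted p = 0.131 with an estimated correlation) and -0.24 without CL 1, with 0 of 11 past the test over all genes or adjusted over the list alone. Tenocyte markers had a median of -0.38 (camera adjusted p = 0.00101; adjusted p = 0.500 with an estimated correlation) and -0.29 without CL 1. Over all genes 0 of 10 passed, and adjusted over the list alone 4 fell, among them Kera, a corneal and tendon proteoglycan (log2 -0.45), and Chad (-0.73). Endothelial markers had a median of -0.11 (camera adjusted p = 0.00708; adjusted p = 0.531 with an estimated correlation), not called without CTL 2 (adjusted p = 0.0775) or CL 2 (adjusted p = 0.171). With p-values adjusted over the list alone 1 of 16 fell, Aqp1, at a log2 fold change of -0.51 ± 0.12 (SE). DESeq2 called Aqp1 over all genes (adjusted p = 0.0238).

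Some clock genes differed in CL as well when adjusted over the list alone. Arntl had a log2 fold change of 0.78 ± 0.16, its partner Npas2 1.48 ± 0.31, Per3 -0.73 ± 0.16 and Cry2 -0.64 ± 0.12 (SE), with adjusted p of 0.608, 0.608, 0.608 and 0.525 over all genes by edgeR. DESeq2 called Arntl (adjusted p = 0.0256), Per3 (adjusted p = 0.0191) and Cry2 (adjusted p = 0.00778). Over all genes 0 of 16 passed by edgeR and 10 had an unadjusted p under 0.05; adjusted over the list alone 2 rose and 8 fell. The list median was -0.28 (camera adjusted p = 0.00386; adjusted p = 0.484 with an estimated correlation) and -0.21 without CL 1, where it was not called (adjusted p = 0.0533). The 7 mitochondrially encoded genes had a median of 0.27 (camera adjusted p = 0.0210; adjusted p = 0.550 with an estimated correlation), with 0 past the test over all genes or adjusted over the list alone. The list was not called without CL 2 (adjusted p = 0.102), CL 3 (adjusted p = 0.105) or CTL 2 (adjusted p = 0.929), where the median fell to -0.0097.

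Several gene groups followed CL 1. Myh3, the embryonic myosin, had 1.18 ± 0.200 CPM in CTL and 12.7 ± 17.6 in CL (SD, n = 3), a log2 fold change of 3.43 ± 1.06 (SE, adjusted p = 0.692) that was 1.08 without CL 1. Its list, myogenic differentiation and embryonic muscle genes, was not called (median 0.29, camera adjusted p = 0.0675), with 0 of 13 past the test over all genes or adjusted over the list alone. Postn, a matrix protein of healing tissue, went from a log2 fold change of 2.33 to 0.50 without CL 1. Extracellular matrix genes had a median of 0.44 (camera adjusted p = 7.02e-07; adjusted p = 0.531 with an estimated correlation), with 0 of 26 past the test over all genes or adjusted over the list alone, and 0.089 without CL 1 (adjusted p = 0.0598). Camera called 21 of 32 lists (13 higher, 8 lower), 0 with an estimated correlation and 5 without CL 1, namely the macrophage, pericyte and smooth muscle, tenocyte, endothelial and mitochondrially encoded lists. Without CL 1 the antigen presentation genes went from 0.43 to 0.021, adipocyte markers from 0.67 to 0.11 (and to 0.17 without CTL 3, adjusted p = 0.368), proliferation genes from 0.49 to 0.16 and the 3 tested lymphocyte markers from 1.70 to 0.38.

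The limbs of the irradiated mice were compared with each other to separate the treated limb from the animal. Cdkn1a was higher in RL by 1.59 ± 0.24 on the log2 scale (SE, adjusted p = 0.0434) and Apln by 2.26 ± 0.29 (SE, adjusted p = 0.0292). Retnla, a secreted product of alternatively activated macrophages, rose from 4.68 ± 0.398 CPM in CL to 13.9 ± 1.04 CPM in RL (SD, n = 3), a log2 fold change of 1.58 ± 0.22 (SE, adjusted p = 0.0338). The interferon response genes Ifi44 and Ifit3 rose by 1.77 (adjusted p = 0.0338) and 1.63 (adjusted p = 0.0348), and the detoxifying epoxide hydrolase Ephx1 by 0.80 (adjusted p = 0.0348). Myf5 fell from 1.03 ± 0.177 to 0.289 ± 0.0473 CPM (SD, n = 3), a log2 fold change of -1.82 ± 0.28 (SE, adjusted p = 0.0434), and the serine protease Htra4 fell by 1.08 (adjusted p = 0.0348). Of these 8 genes, 7 lost their call without CL 2, 8 without CL 3, 8 without RL 1, 6 without RL 2 and 8 without RL 3. Without the mouse of CL 1 and RL 1, 4 lost it, namely Retnla, Ephx1 and Htra4 (adjusted p = 0.0616 each) and Myf5 (adjusted p = 0.0567). Cdkn1a also lost it with DESeq2's size factors in edgeR (adjusted p = 0.0522).

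Satellite cell markers were lower in the irradiated limb than in its partner. Pax7 had a log2 fold change of -1.68 ± 0.30 (SE, adjusted p = 0.0868), which passed with the mouse as a block (adjusted p = 0.0350), without CL 1 (adjusted p = 0.0435) and by DESeq2. Fgfr4, a growth factor receptor of satellite cells, likewise went from an adjusted p of 0.0739 to 0.0309 with the block, at a log2 fold change of -2.90. Of 20 markers 1, Myf5, fell over all genes and 19 did not pass. In the fit without CL 1, 4 fell and 1 rose over all genes, and 0 passed without the mouse of CL 1 and RL 1. With all libraries and adjusted over the list alone 10 fell and 0 rose. The median was -0.33 (camera adjusted p = 2.28e-14; adjusted p = 0.0101 with an estimated correlation). Of 23 p53 target genes 1, Cdkn1a, rose over all genes and 22 did not pass (4 rose without CL 1, and 1 without the mouse of CL 1 and RL 1). With p-values adjusted over the list alone 8 rose and 0 fell, with a median of 0.35 (camera adjusted p = 4.21e-13; adjusted p = 0.00510 with an estimated correlation). The nuclease Aen and Bax were higher by 0.51 and 0.74 with adjusted p = 0.318 and 0.569 over all genes, and Trp53inp1 by 0.57, with adjusted p = 0.555 and 0.0220 with the block. These were the 2 lists called with an estimated correlation.

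Interferon response genes were higher in RL than in CL with a median of 1.43 (camera adjusted p = 4.40e-33; adjusted p = 0.123 with an estimated correlation). Over all genes 2 of 22 rose and 20 did not pass, and adjusted over the list alone 17 rose. In the fit without CL 1, 17 rose over all genes, and 7 did without the mouse of CL 1 and RL 1. Gbp3, an interferon-induced GTPase, and Ifit2 had adjusted p = 0.0513 and 0.0552, and 0.00996 and 0.0151 with the mouse block. Both passed by DESeq2 (adjusted p = 3.25e-04 and 2.83e-04). Antigen presentation genes had a median of 0.56 (camera adjusted p = 6.57e-07; adjusted p = 0.573 with an estimated correlation), 1.15 without CL 1, where 6 rose over all genes, and 0.21 without CL 2. With all libraries 0 of 14 passed over all genes or adjusted over the list alone by edgeR. Macrophage markers had a median of 0.51 (camera adjusted p = 2.70e-06; adjusted p = 0.573 with an estimated correlation), 0.87 without CL 1 and 0.15 without CL 2, where the call ended (adjusted p = 0.0581). Over all genes 0 of 17 passed by edgeR and 4 without CL 1, and adjusted over the list alone 2 rose. Ccr2 and Itgam had adjusted p = 0.0674 and 0.728, and 0.0127 and 0.0220 with the block. DESeq2 called Ccr2 (adjusted p = 1.10e-04). Proliferation genes had a median of 0.38 (camera adjusted p = 0.0264; adjusted p = 0.678 with an estimated correlation), with 0 of 20 past the test over all genes or adjusted over the list alone. That call ended without CL 2 (-9.055e-04), CL 3 (0.25), RL 1 (0.24) or RL 3 (0.28), and the median was 1.04 without CL 1.

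Tenocyte markers were lower in RL by a median of -0.52 (camera adjusted p = 6.10e-08; adjusted p = 0.123 with an estimated correlation). Over all genes 0 of 10 passed, and adjusted over the list alone 8 fell, among them Col11a1 (log2 -0.68), the tendon membrane protein Tnmd (-0.55) and the matricellular protein Thbs4 (-0.55). Slow fibre genes were higher by a median of 0.50 (camera adjusted p = 3.17e-06; adjusted p = 0.504 with an estimated correlation) and by 0.32 without CL 1 (adjusted p = 0.0269). By edgeR 0 of 13 passed over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05. Tnnc1, the troponin of slow fibres, had a log2 fold change of 0.79 (adjusted p = 0.999, and 0.00961 with the mouse block). Fast fibre genes had a median of -0.14 (camera adjusted p = 0.0123; adjusted p = 0.644 with an estimated correlation), with 0 of 15 past the test over all genes or adjusted over the list alone, and were not called without CL 2 (-0.079), CL 3 (-0.046), RL 2 (-0.11) or RL 3 (-0.059), while the median was -0.21 without CL 1. Adipocyte markers had a median of -0.53 (camera adjusted p = 1.35e-04; adjusted p = 0.573 with an estimated correlation), with 0 of 13 past the test over all genes or adjusted over the list alone, and -0.13 without CL 1, where they were not called (adjusted p = 0.210). Myh4 and Col1a1 had log2 fold changes of -0.12 ± 0.17 and -0.99 ± 0.33 (SE), with adjusted p = 0.999 and 0.900.

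Besides the 8 genes above, 3 passed that the naming rule leaves out and that were chosen after their values were seen. Car4, a membrane-bound carbonic anhydrase, fell by 2.47 (adjusted p = 0.0338). The predicted genes Gm10800 (chromosome 2, 98666547 to 98667301, minus strand) and Gm10801 (chromosome 2, 98662237 to 98664083, plus strand), whose transcripts carry the satellite repeat that lies beside mouse centromeres, rose by 5.23 (adjusted p = 0.00173) and 4.53 (adjusted p = 0.0292). Gm10800 had 333 counts in the RL libraries and 14 in the other 6 libraries (95% interval of the scaled ratio 26.9 to 84.5), and reads of these genes cannot be assigned with certainty among near-identical copies.

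In total 11 genes changed between RL and CL, 8 higher and 3 lower, by edgeR, and 639 had an unadjusted p under 0.05. All 11 had groups that did not overlap, as did 1244 tested genes (8.30%, where 10% come by chance). With the mouse as a block, 64 genes changed (50 higher, 14 lower), which include all 11. The authors' deposited table has 49 (34 higher, 15 lower), which also include all 11. The count was 136 without CL 1, 4 without CL 2, 1 without CL 3, and 1, 3 and 1 without RL 1, 2 and 3. Without the mouse of CL 1 and RL 1 it was 20, all higher, with 6 of the 11 among them. Camera called 14 of 32 lists, 7 higher and 7 lower, and 2 with an estimated correlation. With the mouse block it also called myogenic differentiation and embryonic muscle genes (main median -0.16, adjusted p = 0.0478 with the block), denervation response genes (-0.23, adjusted p = 0.0195) and Schwann cell markers (-0.18, adjusted p = 0.0195) lower and mitochondrially encoded genes (0.15, adjusted p = 0.0101) higher. Without the block these 4 had adjusted p of 0.678 to 0.691 with an estimated correlation, and without CL 1 the myogenic and denervation medians turned to 0.045. Beyond those described, the 14 include neuromuscular junction genes (-0.11), mast cell markers (-0.59), erythroid genes (-0.26) and nuclear oxidative phosphorylation genes (0.077), with adjusted p between 0.00485 and 0.0320 (adjusted p of 0.573 to 0.865 with an estimated correlation). Their calls ended without CL 1 or RL 2 for neuromuscular junction genes, CL 1 for mast cell markers, CL 3 or RL 1 for erythroid genes and RL 2 for the oxidative phosphorylation genes, which without CL 1 were called in the opposite direction (median -0.061, adjusted p = 0.0189). Without CL 1 camera newly called lymphocyte markers (1.40 from 0.33, adjusted p = 0.00378), senescence and secretory genes (0.40 from -0.043, adjusted p = 0.0162) and Schwann cell markers (-0.23 from -0.18, adjusted p = 0.0123). With all libraries these had adjusted p of 0.905, 0.919 and 0.678 with an estimated correlation.

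Between comparisons, 8 genes changed the same way in RL vs CTL and in RL vs CL, 7 higher and 1 lower. Independent lists of these sizes would share 0.0267 higher and 0.00541 lower genes. Simulated unchanged groups that share libraries gave a mean of 0.05 and at most 1 shared gene over 20 simulations. Unchanged groups have few calls to share, so this mean is no baseline for lists of 77 and 11 genes. The RL libraries enter both comparisons and are too few to be divided, so part of the excess can come from them. RL vs CTL and CL vs CTL shared 0 genes by edgeR and 12 by DESeq2 (4 higher, 8 lower). Unchanged groups gave a mean of 0.1 by edgeR, with the same limit, and were not simulated for DESeq2. There, independent lists would share 0.0377 higher and 0.0455 lower genes over 28545 genes, of which 16282 had an adjusted p. The CTL libraries enter both comparisons, so independent lists are no fair baseline for the 12. Part of these 12 can come from the shared CTL libraries.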

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

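The differences below were tested by the contrast of RL with CL that was planned before the data were examined, and the exchanges of libraries were chosen after the result was seen. Because both limbs were set against the same control mice, a difference between RL and CL is also a difference between their changes against CTL, and a gene or list stands here when that difference passed. Groups of 3 libraries were too small to test for a single library far from the others.

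Among named genes, the change against CTL was larger in RL than in CL by a log2 of 2.26 for Apln, 1.77 for Ifi44, 1.63 for Ifit3, 1.59 for Cdkn1a, 1.58 for Retnla and 0.80 for Ephx1. It was -1.82 for Myf5 and -1.08 for Htra4. Apln encodes a peptide made by vessels and muscle, and Cdkn1a, Ephx1 and the p53 target genes belong to the damage response, whereas Ifi44 and Ifit3 respond to interferon.

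Among lists, the median difference was 1.43 for interferon response genes, 0.56 for antigen presentation genes, 0.51 for macrophage markers, 0.50 for slow fibre genes, 0.38 for proliferation genes, 0.35 for p53 target genes and 0.077 for nuclear oxidative phosphorylation genes. It was -0.59 for mast cell markers, -0.53 for adipocyte markers, -0.52 for tenocyte markers, -0.33 for satellite cell markers, -0.26 for erythroid genes, -0.14 for fast fibre genes and -0.11 for neuromuscular junction genes. Of these 14 lists, 2 stayed called with an estimated correlation, the p53 target genes (adjusted p = 0.00510) and the satellite cell markers (adjusted p = 0.0101). Without CL 1 the adipocyte, mast cell and neuromuscular junction differences were no longer called, at -0.13, -0.48 and -0.058, and the nuclear oxidative phosphorylation genes were called in the opposite direction (-0.061, camera adjusted p = 0.0189).

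The 6 libraries of each comparison can be divided into equal parts in 10 ways, so the smallest share such a test can reach is 0.1 and it cannot pass by itself. For RL vs CTL the real division gave 77 genes and the other divisions at most 1, so 1 of 10 reached the real count. For CL vs CTL all 10 of 10 did, at 0 genes. For RL vs CL 2 of 10 did, since CL 1, RL 1 and RL 3 against the other libraries gave 134 genes where the real division gave 11, which points to a structure of the samples other than the limb. Among the 4 divisions that part the limbs of every mouse, the 3 besides the real one gave 0 genes.

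Part of the authors' mean signal does not follow from the 9 libraries, and its source was not tested. In the authors' comparison tables, 2058 genes that have 0 counts in all 9 libraries carry a mean signal above 0. For Igkc, an antibody light chain, that mean is 379 where the 9 normalised columns give 71.8.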

How the results depend on the processing

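The alternatives were planned before the data were examined, except that leaving out the mouse of CL 1 and RL 1 and leaving out CL 1 for RL vs CTL were chosen after the result was seen. Of 355 alternative results for called genes, 194 kept direction and call, 161 lost the call and 0 reversed. Of 1213 for genes not called, 1089 stayed so, 119 passed and 5 reversed. Of 582 for called lists, 395 stayed, 181 lost the call and 6 reversed by the direction of the test.

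For RL vs CTL, the 77 changed genes became 333 by DESeq2, 44 by limma-voom, 896 without the filter, 505 with the 2 groups alone, 415 with the replicate number as a block (a number that ties no CTL mouse to an RL mouse) and 291 without that mouse, and 2 to 600 when 1 library was left out. Each of these last fits lacks 1 library, yet 600 came without CL 1, the library farthest from its group, and 5 without RL 1. Leaving out both gave 291, so fewer libraries alone do not explain the lowest counts. Those came from fits that kept CL 1 in the shared spread. For CL vs CTL, 0 became 16 by DESeq2, 716 without the filter and 0 to 1 when 1 library was left out. For RL vs CL, 11 became 38 by DESeq2, 406 without the filter, 49 with the mouse as a random effect, 4 with the 2 groups alone, 64 with the mouse block, 20 without that mouse (20 higher, 0 lower, 6 of the 11 kept) and 1 to 136 when 1 library was left out.

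Called lists went from 20 to 1 with an estimated correlation and 6 by limma's fry for RL vs CTL, from 21 to 0, 1 and, without that mouse, 3 for CL vs CTL (5 to 22 when 1 library was left out), and from 14 to 2 and 2 for RL vs CL. By DESeq2, 34 calls were shared between RL vs CTL and RL vs CL and 12 between RL vs CTL and CL vs CTL.

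Some signs reversed. In CL vs CTL, the nuclear oxidative phosphorylation genes were at 0.069 without CL 1 and 0.074 without that mouse (-0.15 to 0.069 when 1 library was left out), the mitochondrially encoded genes at -0.0097 without CTL 2 (to 0.46), the immediate early genes at -0.011 without CTL 3 (by the median alone), mt-Nd1 at -0.022 without CTL 2 (to 0.46), Pax7 at 0.0039 without CTL 2 and 0.0091 without CL 2 (from -0.31), and Col1a1 at -0.021 without CL 1 and -0.015 without that mouse (to 0.85). In RL vs CL, proliferation genes were at -9.055e-04 without CL 2 (to 1.04) and nuclear oxidative phosphorylation genes at -0.061 without CL 1, a called change in the opposite direction (camera adjusted p = 0.0189), and -0.051 without that mouse (to 0.17). Except for the smaller sets of libraries, the cause was not tested. Depth limits the scarce transcripts, since Chrng and 13 of 16 lymphocyte markers had too few counts to be tested.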

Other observations

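The tests of explanations in this part were chosen after the result was seen, except that 3 predictions, on CL 1 as the source of the clock difference, on genomic DNA and on dividing cells, were written before their tests were run. The edgeR and list tests are the planned ones. The genes named here lie outside the naming rule and were chosen after their values were seen, except Myh3, Retnla, Mki67 and the clock genes.

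The long noncoding RNA gene Gm28653 (chromosome 1, 20669882 to 20684298, plus strand) had higher means in both limbs of the irradiated mice. In the main edgeR fit it passed in RL vs CTL only. It spans Mir206 (20679010 to 20679082) and Mir133b (20682769 to 20682887), which encode muscle microRNAs. It had 0.467 ± 0.394 CPM in CTL, 3.88 ± 0.932 in CL and 3.90 ± 0.832 in RL (SD, n = 3), a log2 fold change of 3.09 ± 0.41 (SE, adjusted p = 0.0131) in RL vs CTL and 3.08 ± 0.41 (SE, adjusted p = 0.105) in CL vs CTL.

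Single genes outside the lists also changed in RL against CTL, and no list of such genes was tested. Ccl6 and Ccl9, which attract myeloid cells, rose by 1.67 (adjusted p = 0.0212) and 1.68 (adjusted p = 0.0216) against CTL, Mgl2, a lectin of alternatively activated macrophages, by 0.94 (adjusted p = 0.0256), and Retnla by 1.43 (adjusted p = 0.0229). The C-type lectins Clec4a1, Clec4a3 and Clec4b1 rose by 1.46, 2.09 and 2.46 (adjusted p = 0.0359, 0.0333 and 0.0308), while Tnfsf10, a death receptor ligand, fell by 0.82 (adjusted p = 0.0252). Of the genes in this paragraph, Retnla alone passed between RL and CL by edgeR (adjusted p = 0.0338). The others had adjusted p between 0.167 and 0.999 there.

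CL 1 carried transcripts of lymphoid tissue. Of the lymphocyte and node stroma genes examined, 87.1% were at least 3 times the highest other library in CL 1, with a summed T cell signal of 23.9 CPM against at most 1.38 CPM elsewhere, in line with a piece of lymph node taken with the muscle (no biological explanation was tested), although the node chemokine genes Ccl21a and Ccl19 had 0 and 2 counts. Left-over blood is excluded, since erythroid genes in CL 1 had a median ratio of 0.722 to CL 2 and CL 3. Gm10800 in CL 1 reached 4.11% of the lowest RL library. That gene was chosen because it separates RL from CL under these labels, so it cannot exclude an exchange of CL 1 with RL 1. Of 7 embryonic muscle genes 4 met the same limit in CL 1 (Myh3 33.0 CPM and 9.78 in RL 1 of the same mouse), while Actc1 was higher in RL 1 (517 CPM) than in CL 1 (490.2 CPM). Their median ratio was 5.19 to the higher of CL 2 and CL 3. This restates that they were high in CL 1 and is no separate test of node tissue as the source. A signal in both limbs of that mouse stays open.

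Some clock genes differed between the irradiated and the control mice in both limbs when adjusted over the list alone. In CL vs CTL 10 of 16 passed so by edgeR and 0 over all genes. CL was not irradiated, so a cause that acts in the irradiated limb alone would leave CL at the CTL levels. The changes in CL argue against such a cause for these 10 genes, although the same passes define the pattern. The list was not called by camera without CL 1 (adjusted p = 0.0533), with an estimated correlation (adjusted p = 0.484) or by fry (adjusted p = 0.111). Without CL 1, 9 of 16 still passed over the list alone, and the 10 kept 94.3% of their median change (0.60 and 0.57), so CL 1 alone is excluded. Between RL and CL 0 passed by edgeR, and 0 had an unadjusted p under 0.05. A difference in time of day or handling at collection and a response of the whole irradiated animal could each give this, and the design cannot tell them apart, since irradiated and control mice are different animals.

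Transcripts with the satellite repeat found beside mouse centromeres were high in the irradiated limbs alone. Their sum over 13 genes was 4.48 to 4.99 CPM in RL and at most 0.327 CPM elsewhere, a ratio of means of 28.8. Reads moved among these 13 genes would leave their sum unchanged, so such moves alone cannot give the ratio. Copies of the repeat outside the annotated transcripts were not counted, so reads shared with them are not excluded. For genomic DNA in the RL libraries, 1956 olfactory and vomeronasal receptor genes, silent in muscle, had a ratio of 1.16. This cannot exclude DNA, since a repeat with many more copies than these genes could gain reads where they do not. Dividing cells remain open, since the lowest RL ratio of these transcripts to Mki67 was 2.66 times the highest elsewhere, yet few libraries have high Mki67; CL 1, with the most (10.4 CPM), had 0.288 CPM. The ratio of 28.8 may follow from irradiation of the limb, since CL of the same mice lacked the signal, and the mechanism was not tested.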
